A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

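Total RNA of Saccharomyces cerevisiae S288c was taken per the labels after 5 h with 15 µM tomatidine, 7.5 µM tomatidine or the solvent DMF alone, with 1 array per condition. The deposited table holds 1 intensity per probe set and array on a linear scale, the summary signal of the probe set, which the authors made before deposit. The summary method, its detection calls, its background correction and its scaling are not given in the sources used here. The deposited intensity values themselves show a global scaling, since the mean without the lowest and highest 2% of probe sets was 100.1 on each array. Such a scaling sets the mean level equal, so that a change of total messenger RNA cannot be seen. Values at 0 numbered 7, 7 and 4 on the 15 µM, 7.5 µM and control arrays.

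Of 9335 probe sets, 60 were controls. In the given annotation 6504 had 1 gene, 328 had several genes and 2443 non-control probe sets had no entry. No gene was named from a probe set with several genes in that annotation. Probe sets were not filtered by type. Some named genes, such as HXT6, PAU23, ERG12 and TPO2, were read by types other than the plain one, which is designed without shared probes. All 6504 single-gene identifiers matched the gene table of the R64 assembly, which was used for symbols and for which genes neighbour each other. No genome build is named by the data, so no coordinates are given. Of 5656 genes, 315 had more than 1 probe set, and the brightest over the 3 arrays was used.

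Each array was divided by its median over non-control probe sets and brought to a common level (factors 0.974, 0.986 and 1.04 for 15 µM, 7.5 µM and control). Signals were then floored at the 40th percentile of the pooled scaled signals (18.2) and put on the log2 scale. A gene was called at 2-fold or more with the brighter array above the floor, and where the dimmer array was at or under the floor the fold is given as at least that value. This rule of size takes the place of a test. On simulated arrays with known changes it recovered 94.0% of 50 genes changed 2.5-fold and 100.0% of 50 changed 4-fold, for 15 µM over control. Of 50 changed 1.5-fold it recovered 4.0%. It called 9 unchanged genes, with 4563 genes compared, the changed ones included. All changed genes had signals well above the floor, so the recovery of dim genes was not measured. Noise was drawn separately for each probe set, so differences between cultures that many genes share are not in these numbers. Its size was a robust spread, which leaves out rare large differences, so the 9 may be too low. The simulations of the shared control described below took the larger of a robust and an ordinary SD. On average they called 9.64 higher and 9.94 lower unchanged genes for 15 µM over control.

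Fixed before the data were examined were 36 gene lists of sterol, stress, nutrient, growth and cell state genes, the rule of size, and the rule for named genes. That rule took the 12 largest ratios in each direction at 15 µM among called genes that also differed by 1.5-fold in the same direction at 7.5 µM (102 higher and 40 lower genes qualified), the 5 largest in each direction for the other comparisons, up to 4 members of each described list, and every sterol synthesis gene. Further members named to describe a list were chosen after their values were seen. For each list the median log2 ratio was set against 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. A 95% bootstrap interval of each median came from 2000 draws over the list's members. The listed genes that were used had a probe set annotated to 1 gene and were above the floor on at least 1 array. Together these conditions left 80 of 137 ribosomal protein genes, and for 1 list 1 member.

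For the shared control, 100 simulations drew unchanged doses with the spread seen between the treated arrays. The spread of ratios between probe sets of one gene was pooled over 173 genes with at least 2 probe sets above the floor. Alternatives were the values as deposited, quantile normalisation, lowess centring of log2 ratios on signal (span 0.3), floors at the 20th and 60th percentile, no floor with a pseudocount at the 5th percentile, the mean of all probe sets of a gene, a 3-fold rule, and a rule beyond 3 robust SDs. Scaling on 8 spike probe sets of bacterial and phage origin was added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.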

Results

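Gene expression was measured in Saccharomyces cerevisiae S288c, the reference laboratory strain of baker's yeast, after 5 h in 3 conditions. Cells received 15 µM tomatidine, 7.5 µM tomatidine, or only dimethylformamide (DMF), the solvent in which the compound was given. Tomatidine is a steroidal alkaloid, the sugar-free part of the tomato glycoalkaloid tomatine. Total RNA of each condition was hybridised to 1 Affymetrix yeast array with 9335 probe sets, so 3 arrays were compared. With 1 array per condition there was no replicate, no test and no p-value, and every difference below describes these arrays; their number limits the precision.

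The deposited signals had medians of 30.4, 30.1 and 28.5 on the 15 µM, 7.5 µM and control arrays. Of 5656 genes with a probe set annotated to them alone, 4724 were above the signal floor on at least 1 array and were compared. The floored log2 signals of the arrays were correlated across all 9275 non-control probe sets, which are not independent replicates. The correlation was 0.988 between the doses, 0.974 between 15 µM and control and 0.980 between 7.5 µM and control. The 3' to 5' signal ratio of the actin gene ACT1, a sign of RNA integrity, was 1.47, 1.80 and 1.63 on the 15 µM, 7.5 µM and control arrays, and that of SPT15, the TATA-binding protein gene, was 2.48, 2.35 and 3.30. Spike controls of bacterial and phage origin were added before hybridisation. The geometric means of their deposited signals were 126, 138 and 211 on the 15 µM, 7.5 µM and control arrays. After each array was scaled to its median, they were 1.78-fold brighter on the control array than on the 15 µM array. Against the 7.5 µM array they were 1.61-fold brighter. All folds below are relative to the median probe set of each array, not to the spikes.

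The first comparison asked which transcripts differed after 5 h in 15 µM tomatidine. Genes of sterol synthesis and sterol uptake were higher than in the solvent control, together with genes of the phosphate regulon and of the general stress response, while genes of purine synthesis and of the pheromone response were lower. DAN4, a cell wall mannoprotein gene of cells without oxygen, was 35.5-fold higher, from a scaled signal of 25.7 to 914. CYB5, cytochrome b5, an electron donor in sterol synthesis, was 4.52-fold higher, and PHO5, the secreted acid phosphatase, 4.30-fold higher. TIP1, another cell wall mannoprotein gene, was 8.79-fold lower, from 1211 to 138. In all, 129 of 4724 genes were at least 2-fold higher and 54 at least 2-fold lower, and in 18 and 6 of these the dimmer array was at the floor, so that the fold is a lower bound. With the arrays scaled on the spikes in place of the median, 1288 genes were higher and 7 lower.

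The 16 measured genes that lead from squalene synthesis to ergosterol, the main sterol of yeast membranes, had a median log2 ratio of 1.09 at 15 µM. All 16 lay above 0, 10 were at least 2-fold higher and 6 were not. Besides CYB5, the largest ratios were those of ERG28, a scaffold protein of the sterol C4 demethylation complex (2.16), ERG26, a C3 sterol dehydrogenase (1.55), ERG24, the C14 sterol reductase (1.49), and ERG1, squalene epoxidase (1.35). ERG9, squalene synthase (1.24), ERG4 (1.11), ERG7 (1.10), ERG27 (1.08) and ERG3 (1.06) were also at least 2-fold higher. Below 2-fold lay ERG5 (0.97), ERG2 (0.93), ERG6 (0.82), ERG25 (0.75), NCP1 (0.65) and ERG11, the lanosterol demethylase (0.39). The median exceeded that of every one of 10000 random lists of the same size matched on signal, whose central 95% ran from -0.33 to 0.07.

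The 9 genes of the mevalonate pathway, which supplies the precursors of squalene, differed less, with a median log2 ratio of 0.34 (percentile 99.7). ERG8, phosphomevalonate kinase, was 2.38-fold higher and the other 8 were below 2-fold. Values ranged from 0.61 for ERG20, 0.58 for ERG10, 0.43 for ERG13, 0.34 for MVD1 and 0.24 for ERG12 to 0.07 for HMG1, -0.15 for IDI1 and -0.17 for HMG2, the last of which encodes an HMG-CoA reductase isozyme.

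**Figure D1:**
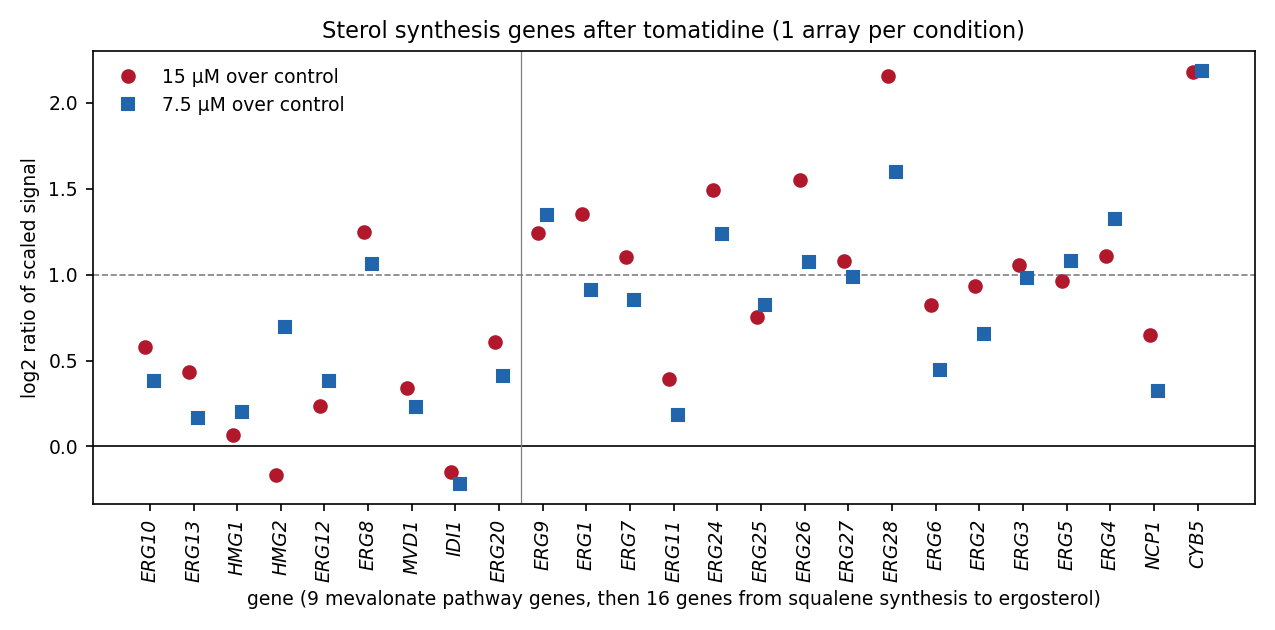
Log2 ratio of scaled signal (y axis) for each sterol synthesis gene (x axis, mevalonate genes left of the vertical line) at 15 µM (circles) and 7.5 µM (squares) over the solvent control, 1 array each, with 2-fold dashed. All 16 genes from squalene synthesis onward lie above 0 at both doses, and among the 9 mevalonate genes ERG8 alone reaches 2-fold.

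The list of sterol uptake genes and cell wall mannoproteins of low oxygen had a median log2 ratio of 1.42 at 15 µM over 13 measured members (percentile 100), with 9 called at least 2-fold higher and 4 not. Besides DAN4, DAN1 was at least 24.8-fold higher, HES1, an oxysterol-binding protein homolog, at least 5.43-fold, and TIR3 4.67-fold. The sterol importers PDR11 and AUS1 were 2.67-fold and 2.33-fold higher. Of the transcription factor genes of the list, UPC2 was at least 1.59-fold higher, with its control signal under the floor, and ECM22 and SUT1 had log2 ratios of -0.49 and -0.42. Of 17 sterol storage and transport genes 3 were at least 2-fold higher, ATF2, an acetyltransferase that acts on sterols (5.65-fold), YEH1, a steryl ester hydrolase (2.70-fold), and NCR1 (2.02-fold). The median of that list, 0.06, was inside the central 95% of random lists.

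Other lists also had medians above those of random lists. In the phosphate regulon (median 0.59, 11 of 13 above 0) 5 were at least 2-fold higher, among them PHO5, PHO89, a sodium phosphate cotransporter (4.15-fold), and PHM6 (2.75-fold), while PHO84, the high affinity phosphate transporter, had a log2 ratio of -0.07. In the general stress list (median 0.56, 21 of 25 above 0) 6 were higher, 1 was lower and 18 were neither. PGM2, phosphoglucomutase (3.75-fold), and the small heat shock genes HSP26 (3.72-fold) and HSP12 (2.94-fold) were higher, and MSN4, a stress transcription factor gene, was at least 2.27-fold lower. Of 17 drug resistance genes (median 0.54, 12 above 0) 3 were higher and 1 lower. ICT1 was 3.90-fold higher and the transporter gene PDR15 at least 3.67-fold, the weak acid transporter gene PDR12 was 2.77-fold lower, and the multidrug transporter gene PDR5 had a log2 ratio of 0.59. The lists of arginine, lysine, histidine and tryptophan synthesis (median 0.29, with 2 of 21 at least 2-fold higher, ARG1 and LYS9) and of sulfur amino acid synthesis (median 0.21, with none of 19 higher and 1, MUP3, lower) were also above the central 95% of random lists, the second no longer so with the arrays scaled on the spikes.

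Purine synthesis genes were lower, with a median log2 ratio of -0.79 over 11 measured members (percentile 0) and 10 of 11 below 0. ADE1, ADE13 and MTD1 were 2.17-fold, 2.12-fold and 2.08-fold lower, and the other 8 were below 2-fold. In the pheromone response list all 12 measured members lay below 0 (median -0.63, percentile 0), and 5 were at least 2-fold lower. These were AGA1, an agglutinin anchor subunit (log2 ratio -1.60), FUS1, a cell fusion protein (-1.59), the alpha-factor gene MF(ALPHA)2 (-1.46), SST2 (-1.46) and FUS3, the mating MAP kinase (-1.32). SAG1, the alpha-agglutinin gene outside the list, was 3.80-fold lower.

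In the respiratory chain list 26 of 30 members lay below 0, with a median of -0.31 (percentile 0), and none was 2-fold lower. The lowest were CYC1 (-0.98) and COX8 (-0.95). HAP4, an activator of respiratory genes, was at least 3.39-fold lower. Of 80 cytosolic ribosomal protein genes 70 lay below 0 and none reached 2-fold. Their median was -0.34 (percentile 0.41), but -0.08 after signal-dependent centring, and it lay inside the random range with quantile normalisation. Heat shock chaperone genes had a median of -0.30 (percentile 1.04) with none of 19 at 2-fold, and were inside the random range with the floor at the 60th percentile or spike scaling.

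The 9 measured hexose transporter and sensor genes moved apart. The low affinity transporter genes HXT1 and HXT3 were 2.53-fold and 1.83-fold higher. HXT6, HXT7 and HXT4 were lower, with log2 ratios of -2.14, -1.32 and -1.21. HXT6 and HXT7 are near-identical copies read by probe sets of the family type, so that each value is uncertain. The median of the list was 0.27 and its mean -0.22, and the median turned to -0.59 with the floor at the 60th percentile and to -0.13, relative to all genes, with spike scaling.

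Besides the genes above, the named genes with the largest folds at 15 µM were PBI1 (at least 15.6-fold higher), TSA2, a thioredoxin peroxidase (14.0-fold), YPR145C-A (at least 9.54-fold), YSR3, a dihydrosphingosine phosphate phosphatase (8.43-fold), GSC2, a beta-glucan synthase subunit (8.11-fold, but a log2 ratio of 1.04 with its 7 probe sets averaged, 4 of them under the floor), FHN1 (at least 7.82-fold), YMR317W (at least 7.68-fold) and AMS1, the vacuolar alpha-mannosidase (6.26-fold). TSA2 and GSC2 belong to the oxidative stress and cell wall integrity lists, in which they were the only members at 2-fold or more, and both list medians were inside the random range. Among the lower genes, the polyamine transporter gene TPO2 was at least 4.23-fold lower, NFG1 3.77-fold, ARO10, a decarboxylase of aromatic amino acid breakdown, at least 3.62-fold, the aquaporin gene AQY2 3.54-fold and GAT2 3.33-fold, and DUS3 had a log2 ratio of -1.58. TIP1, HXT6, HAP4, AGA1, FUS1 and SAG1 completed the 12 lower genes.

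Of the 36 lists, 9 had medians above the central 95% of random lists at 15 µM and 5 below it, against 0.9 expected on each side by chance. That expectation takes the members of a list to vary independently of each other. Differences between cultures that members share are not in it and could also place lists outside. The bootstrap intervals over members of the mevalonate (-0.15 to 0.61), drug resistance (-0.10 to 0.87) and hexose (-1.32 to 0.87) lists spanned 0, and that of the sulfur amino acid list reached it. Among those inside, the heme and oxygen list had a median of 0.23, at the upper end of its random range, with HEM13, coproporphyrinogen oxidase, at 2.43-fold, while the low oxygen genes ANB1 (0.03), COX5B (0.10) and AAC3 (-0.91) were below 2-fold. Fatty acid synthesis (-0.16), with ELO1, a fatty acid elongase, 2.86-fold lower, and the iron (-0.18), zinc (-0.23), unfolded protein (0.07), phospholipid (0.05), sphingolipid (0.01), beta-oxidation (0.26), ribosome biogenesis (-0.18), tricarboxylic acid cycle (-0.23) and gluconeogenesis (0.03) lists were also inside. So were the oxidative stress (-0.04), cell wall integrity (-0.17), branched amino acid (-0.06), nitrogen (0.03), thiamine (0.10), histone (0.09), G1 and replication (-0.18) and mitotic (-0.24) lists. Glycolysis was inside at -0.25, and its median was 0.04 with quantile normalisation and with signal-dependent centring. The meiosis list had 1 measured member, IME1 (at least 1.06-fold lower). Median and mean differed in sign for 7 lists.

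**Figure D2:**
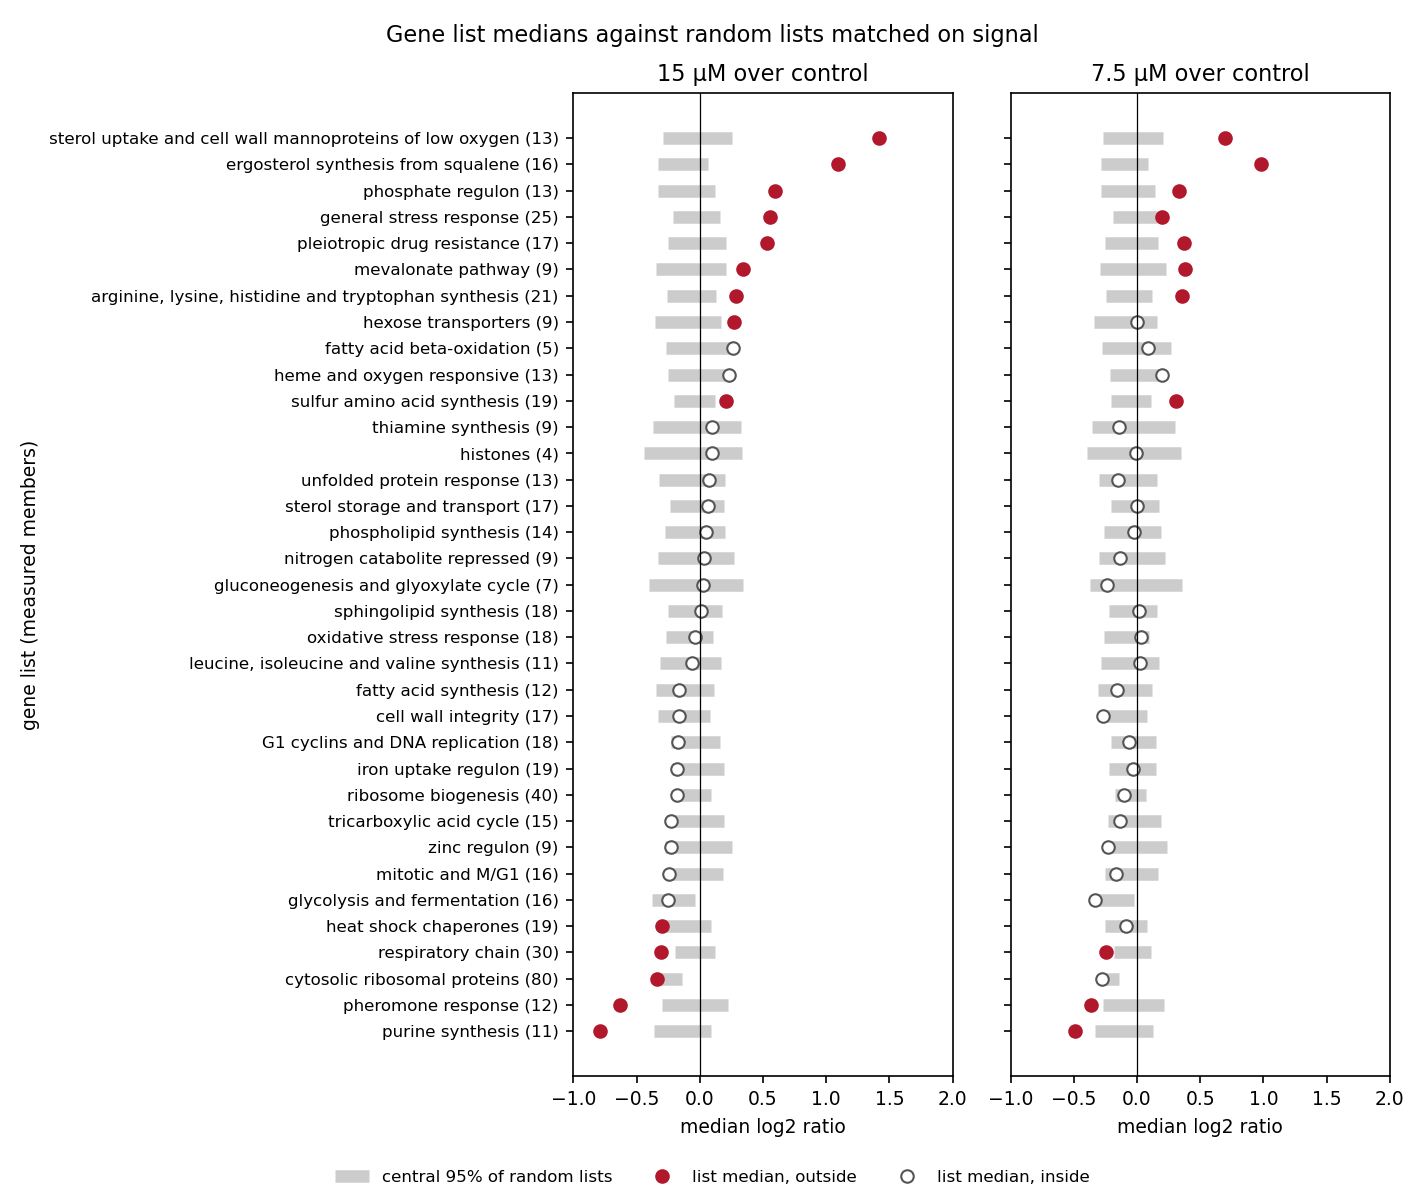
Median log2 ratio (x axis) of each gene list with at least 3 measured members (y axis, number of measured members in brackets) at 15 µM (left) and 7.5 µM (right) over the solvent control. Grey bars are the central 95% of 10000 random lists matched on signal, filled circles medians outside it. The sterol uptake and mannoprotein list (1.42 and 0.70) and the ergosterol list (1.09 and 0.98) lie farthest to the right. Purine synthesis (-0.79 and -0.49) lies farthest to the left.

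As a stand-in for the missing replicates, the ratios of probe sets that read the same gene had a pooled SD of 0.38 log2 units over 173 genes at 15 µM. This covers differences between probes on the same RNA and no difference between cultures. The 60th percentile floor took TPO2, NFG1, ARO10, AQY2, HAP4, GAT2, FUS1 and DUS3 below 2-fold, since their control signals lay near it. DAN4, TSA2 and AMS1 stayed at least 2-fold higher at 15 µM. That floor lies above their control signals, so their folds are smaller with it.

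The second comparison asked what the lower dose did. At 7.5 µM, the medians of the sterol synthesis lists and of the sterol uptake and mannoprotein list were again above the control. The purine synthesis median was below it. The sterol storage and transport list had a median of 0 over 17 members, inside the random range. DAN4 was 20.1-fold higher, DAN1 at least 16.9-fold, PBI1 at least 7.13-fold, TSA2 6.22-fold and YMR317W at least 5.68-fold. TIP1 was 4.29-fold lower, TPO2 at least 4.23-fold, AQY2 3.67-fold, ARO10 at least 3.62-fold and NFG1 3.05-fold, and of these TPO2, AQY2, ARO10 and NFG1 were below 2-fold with the 60th percentile floor. In total 93 genes were at least 2-fold higher and 29 at least 2-fold lower, 11 and 4 of them with the dimmer array at the floor. The split was 125 and 19 with the values as deposited and 797 and 4 with spike scaling.

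The ergosterol list had a median log2 ratio of 0.98 at 7.5 µM (percentile 100), with all 16 members above 0 and 7 at least 2-fold higher. ERG28 was 3.03-fold higher, and log2 ratios were 2.18 for CYB5, 1.35 for ERG9, 1.32 for ERG4, 1.23 for ERG24, 1.08 for ERG5 and 1.07 for ERG26. Those of ERG11 (0.18), NCP1 (0.32) and ERG6 (0.45) were the lowest. In the mevalonate pathway (median 0.38, percentile 99.6) ERG8 was 2.08-fold higher, and HMG2 had a log2 ratio of 0.69. Of the sterol uptake and mannoprotein list (median 0.70, percentile 100) 5 of 13 were at least 2-fold higher, namely DAN4, DAN1, HES1, TIR3 and TIR1. The sterol importers PDR11 and AUS1 were at 1.82-fold and 1.23-fold. Of the transcription factor genes, UPC2 was at least 1.17-fold higher, and ECM22 and SUT1 had log2 ratios of 0.11 and -0.22.

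Phosphate regulon genes had a median of 0.34, above the random range, with 4 of 13 at least 2-fold higher, PHO5 (3.74-fold) and PHO89 (3.50-fold) first. The arginine, lysine, histidine and tryptophan list had a median of 0.36 with 3 of 21 higher, ARG1, argininosuccinate synthase (4.09-fold), LYS2 (2.34-fold) and ARG4 (2.33-fold). Sulfur amino acid genes had a median of 0.31 with 2 of 19 higher, MET14 and MET3. The drug resistance (0.37) and general stress (0.20) lists were above the random range too, the first not with all probe sets of a gene averaged or with spike scaling, the second not with the 60th percentile floor. Below the random range lay purine synthesis (-0.49, with 1 of 11 at least 2-fold lower, ADE17), the pheromone response (-0.36, 2 of 12, AGA1 and FUS1) and the respiratory chain (-0.25, none of 30). Ribosomal protein genes had a median of -0.28 at percentile 5.96. The bootstrap intervals of the drug resistance (-0.01 to 0.62), general stress (-0.07 to 0.63) and pheromone (-0.75 to 0.07) lists spanned 0, the last with 4 of 12 members above 0. In all, 8 lists lay above and 3 below, and the pooled SD between probe sets of a gene was 0.34.

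The third comparison set the doses against each other, which involves no control array. The general stress list and the sterol uptake and mannoprotein list were higher at 15 µM than at 7.5 µM, and the pheromone response list lower. YPR145C-A was 3.87-fold higher at 15 µM, AMS1 3.86-fold, MNC1 at least 3.62-fold, GSC2 3.58-fold and YPL088W 3.13-fold. RPT6, a proteasome ATPase, was 3.05-fold lower at 15 µM, MPC1, a subunit of the mitochondrial pyruvate carrier, 2.71-fold, STE23, a protease of a-factor maturation, 2.52-fold, LEC1 2.32-fold and SST2 2.15-fold. There were 34 genes at least 2-fold higher at 15 µM, 8 of them with the dimmer array at the floor, and 13 at least 2-fold lower. Spike scaling gave 68 and 4. The call of GSC2 ended when all its probe sets were averaged (0.62), and those of MNC1, YPL088W, STE23 and LEC1 ended with the 60th percentile floor.

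The sterol uptake and mannoprotein list had a median log2 ratio of 0.55 at 15 µM over 7.5 µM (percentile 100), with 11 of 13 above 0. TIR4 was at 2.87-fold, the importers AUS1 and PDR11 had log2 ratios of 0.92 and 0.55, and ECM22 and SUT1 lay below 0 (-0.60 and -0.20). The general stress list followed with 0.32 over 25 members (percentile 100), 20 above 0. The ergosterol list had a median of 0.23, above the random range of -0.18 to 0.12, with 11 of 16 above 0 and none at 2-fold, with CYB5 at -0.01, ERG9 at -0.11 and ERG4 at -0.22. Sphingolipid (0.18) and phosphate (0.17) lists were also above the random range. In the pheromone list all 12 members were lower at 15 µM (median -0.52, percentile 0). The arginine, lysine, histidine and tryptophan list (-0.31), purine synthesis (-0.23), heat shock chaperones (-0.19) and ribosome biogenesis (-0.14) also lay below it, the first and the second of these not with the 60th percentile floor. The bootstrap intervals of the ergosterol (-0.01 to 0.33), phosphate (-0.03 to 0.22), arginine, lysine, histidine and tryptophan (-0.37 to 0.01) and purine (-0.41 to 0.11) lists spanned 0. The pooled SD between probe sets of a gene was 0.29.

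Across the 4724 genes, the log2 ratios of both doses against the control correlated at 0.749. Since both used the same control array, unchanged doses simulated against it gave 0.50 on average. The covariance was 0.156, against 0.053 simulated, a difference of 0.103. Among the calls, 57 genes were at least 2-fold higher and 18 at least 2-fold lower, at both doses. The simulation gave 0.86 and 1.01, and independent lists 2.54 and 0.33. No gene was called in opposite directions, but such a call needs a larger gap between the doses than the largest one seen, 3.87-fold. Its absence therefore adds nothing. The simulation gave the control array the same spread as the treated arrays, drawn gene by gene. A control array or culture with a larger error would raise these values without any effect of tomatidine. The control could not be split, so part or all of the excess may come from it. Of the 129 genes higher at 15 µM, 126 were on the same side at 7.5 µM and 115 were farther from the control at 15 µM, with a median share of 0.693 of the 15 µM log2 ratio at 7.5 µM. Of the 54 lower genes these numbers were 53, 48 and 0.650. These genes were chosen by their value at 15 µM, which favours that array.

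**Figure D3:**
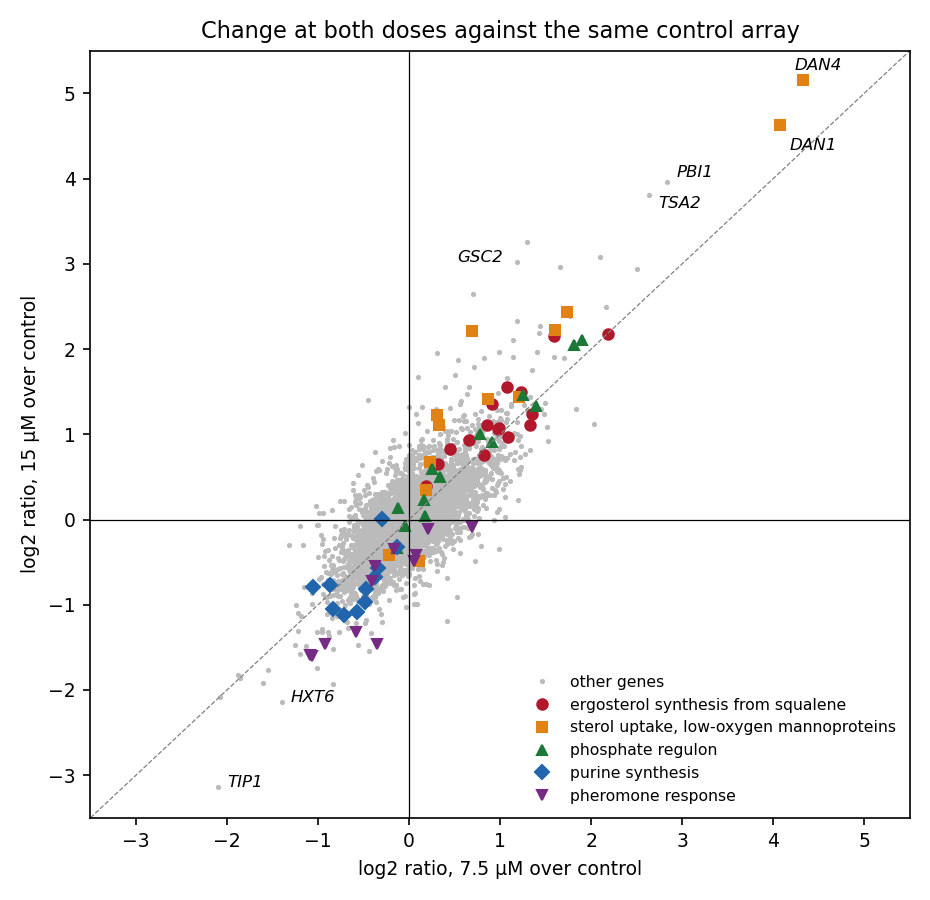
Log2 ratio of each gene above the floor on at least 1 array at 15 µM (y axis) against 7.5 µM (x axis), both over the same control array, with the members of 5 lists marked and the diagonal dashed. DAN4 (5.15 and 4.33) and DAN1 (4.63 and 4.08, both lower bounds) lie at the upper right, TIP1 (-3.14 and -2.10) at the lower left.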

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

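The tests of the shared control array and of the scaling were chosen only after the result was seen, while those of signal-dependent differences and of shared probes were set before.

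Both MNC1 and RPT6 lay on opposite sides of the control at the 2 doses. MNC1 had a log2 ratio of 1.41 at 15 µM and of -0.45 or lower at 7.5 µM, where its signal was under the floor, a gap of at least 1.86 that fell to 0.53 with the 60th percentile floor. RPT6, a proteasome ATPase gene, had -1.19 and 0.42, a gap of -1.61. Also on opposite sides were MPC1 (-0.91 at 15 µM and 0.53 at 7.5 µM), STE23 (-0.35 and 0.99) and LEC1 (-0.48 and 0.73). The other genes named for the comparison of doses, YPR145C-A, AMS1, GSC2, YPL088W and SST2, lay on the same side at both. These differences were not tested, since each dose had 1 array. The bacterial and phage spikes, which serve only in the alternative scaling, were 1.78-fold brighter on the control array than on the 15 µM array after median scaling. Among probe sets outside the gene comparisons, 19 that match several genes and 9 without an annotation entry were at least 2-fold higher at both doses. Of the 243 several-gene probe sets above the floor on an array 33 were higher at 15 µM, which is 13.6%, against 2.73% of the named genes. Several of these probe sets may read the same gene family, so the 33 are not separate genes and the percentages compare unlike units.

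All differences from the control rest on 1 control array, and its error would enter both doses alike. Chance error that is independent from gene to gene is argued against for the ergosterol list by its median of 0.98 at 7.5 µM, above all 10000 matched random lists. Compared without the control, the doses differed for the sterol uptake and mannoprotein list (0.55) and the pheromone list (-0.52). A peculiar control cannot produce a gap between the doses, which argues against it as the whole cause at 15 µM for these lists. The gap between 7.5 µM and the control is not covered by this, and each dose rests on 1 array. For the ergosterol list the same comparison gave 0.23 with a bootstrap interval from -0.01 to 0.33, so a control culture with low sterol gene expression and an effect of tomatidine cannot be told apart. Over all genes at least 2-fold higher at 7.5 µM the median ratio of 15 µM over 7.5 µM was -0.047, and over the lower ones 0.051. These genes were chosen by their value at 7.5 µM, which by itself pushes the ratio between doses towards 0 or past it, so this decides nothing about the control array.

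The respiratory chain and ribosomal protein lists were lower at 15 µM by small amounts shared by many bright genes. After lowess centring the respiratory list kept a median of -0.28 against -0.31 before, with a bootstrap interval from -0.37 to -0.16 that lies below the random range, which argues against a signal-dependent difference between arrays as its whole cause. For the ribosomal list the median went from -0.34 to -0.079, with an interval from -0.10 to -0.01 that spans the lower end of the random range, -0.078; the bound set beforehand was passed, but by less than this spread, a requirement added once the value was known, so the question stays open. With the arrays scaled on the spikes the respiratory median became 0.53, and -0.22 relative to all genes, the measure used at first. Since 1 factor per array fixes both outcomes, neither decides whether the absolute amount fell, and only the position relative to other genes is shown. A response of respiration to tomatidine stays open and untested.

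For the DAN and TIR mannoprotein genes, near-identical family members could share probes. Of the 6 called at 15 µM among 7 measured, 5 were read by probe sets of the plain type, designed without shared probes, which argues against shared probes as the cause for these 5. PAU23 is the exception, and TIR2, not called, had 0.35 on a plain probe set. Of low oxygen genes outside the family HEM13 was higher (1.28), while ANB1 (0.03), COX5B (0.10) and AAC3 (-0.91) were not by 2-fold. Whether sterol shortage or low oxygen may underlie the higher family genes stays open.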

How the results depend on the processing

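The scaling on spikes was chosen only after the data were seen. No paired analysis was possible because each condition had 1 array. The ergosterol list medians kept their direction and place under every alternative, from 1.09 to 1.23 at 15 µM, 0.98 to 1.10 at 7.5 µM and 0.23 to 0.25 between doses. These ranges take spike scaling relative to the shift of all genes; without that subtraction its medians were 1.93, 1.67 and 0.38. The numbers of lists outside the random range also stayed within 1.5 times. Counts of 2-fold genes depended on the floor and on the scaling. In the order higher and lower at 15 µM, at 7.5 µM and between doses, a 20th percentile floor gave 202, 143, 157, 127, 119 and 53 genes. A 60th percentile floor gave 85, 27, 56, 10, 10 and 7, since fewer dim genes can reach 2-fold. No floor with a pseudocount gave 282, 209, 220, 237, 254 and 121. The 3-fold rule gave 38, 11, 19, 5, 5 and 1. Spike scaling gave 1288, 7, 797, 4, 68 and 4, as it shifts the median log2 ratio of all genes by 0.78, 0.63 and 0.14. Beyond 3 robust SDs, 31 genes were lower at 15 µM and 15 at 7.5 µM, and the values as deposited gave 19 lower at 7.5 µM. The correlation between doses was 0.702 with the 20th percentile floor and 0.624 with no floor. The cause was not tested except where given. The hexose transporter median at 15 µM reversed to -0.589 with the 60th percentile floor, where fewer members are measured, and to -0.127 relative to all genes with spike scaling, cause not tested. Of 94 ratios of named genes 34 moved by more than the spread between probe sets in at least 1 alternative. Of the other list medians over all alternatives, 800 stayed inside their bootstrap interval over members, which for some lists spans 0, and 35 moved out of it. A reversal was counted only for lists outside the random range, with 2 cases. Sign changes of lists inside that range, such as glycolysis, are not counted as reversed. Signal over background limits dim genes, as 932 of 5656 were at or under the floor on all arrays.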

Other observations

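The test of the PAU genes was chosen only after the data were seen. The PAU genes are a large family of seripauperin mannoproteins, many of them known from cells without oxygen. Of 10 measured by probe sets annotated to them alone, of any type, 4 were at least 2-fold higher at 15 µM and none at 7.5 µM. The medians relative to the control were 0.76 and 0.07. All 10 lay above 0 at 15 µM over 7.5 µM, from 0.16 to 1.18, with a median of 0.74. Members are close in sequence, so these are not 10 separate measurements. AGA1, FUS1, SAG1 and MF(ALPHA)2, genes of mating cells of the alpha type or of both types, had lower signals at 15 µM than at 7.5 µM, by log2 ratios of -0.53, -0.50, -1.09 and -0.54.

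Genes that were at least 2-fold higher at 15 µM may lie side by side more often than by chance. Among the 129, 7 pairs were direct neighbours in the R64 gene table, against a mean of 2.88 and an upper limit of 6 for the central 95% of 10000 random sets matched on signal. The pairs include DAN1 and DAN4, ERG1 and ATF2, ARI1 and AMS1, and TIR3 and DOT5. DAN1 and DAN4 are related in sequence, and the excess is of a few pairs, so this is a hypothesis for other data.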
